A study of Narcissus tazetta subsp. chinensis with 8 samples.

How the data were processed

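RNA was sequenced from flowers of Narcissus tazetta var. chinensis cv Jinzhanyintai, a Chinese narcissus, in 8 libraries. Per the labels, corolla and petal were each collected on day 1, at early flowering, and on day 7, at full bloom, with 2 biological repeats of each. The labels do not say how many flowers or plants went into a repeat, nor how corolla was separated from petal. The limma p-values given below therefore measure the spread between these repeats only. Fisher's exact tests count genes measured in the same libraries as independent units, so their p-values hold no spread between repeats. Poly-A RNA was made into libraries with an Illumina kit, and the reads were assembled de novo, per the labels. No genome was used here, so genes carry the identifiers of the assembly and have no coordinates.

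For each tissue the authors deposited 3 tables. The table of all genes gives FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) rounded to 2 decimals, an authors' FDR, which is an adjusted p-value, and an authors' log2 fold change, per the file headers and the values. It lists 64490 genes for corolla and 67182 for petal, none at 0 in all 4 libraries of the tissue. The other 2 tables hold the genes the authors called, with read counts as well as FPKM per the file headers. From the values, these deposited tables hold genes with an FDR below 0.01 and at least a 2-fold change. They name 1707 genes for corolla and 1053 for petal, and descriptions from Swiss-Prot, Nr and Gene Ontology are given for 1517 and 880 of them. Bowtie and RSEM are named per the submitters' processing notes, with no version. The tool behind the authors' fold changes and p-values is not given in the sources used here.

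The design fixed before the data were examined called for edgeR on counts, with limma on log2 values if the full tables held FPKM alone. The full tables held FPKM, so the main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a trend in the prior variance, a two-sided moderated test and Benjamini-Hochberg adjustment at FDR 0.05. Genes with at least 1 FPKM in at least 2 of the 4 libraries of a tissue were tested. Fold changes are therefore on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes. The difference of the day effect between corolla and petal was tested as the interaction term over all 8 libraries, for genes in both tables (50576). Of these genes, 26460 had at least 1 FPKM in at least 2 of the 8 libraries, of either tissue, and entered that test. That test had been planned for counts alone and was moved to limma after the unit was known. Contrasts of corolla with petal within a day were not run, because they had been planned for counts only. The planned DESeq2 fit and count filter over all genes could not be run on FPKM. edgeR 4.0.16 and DESeq2 1.42.0 were used only on the counts of the called genes. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 served for the tables, the Fisher tests and the plots.

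The fitting code was tested on simulated data, with 100 genes changed 2-fold and 100 changed 4-fold for each test. In corolla (22407 genes) it recovered 40% of the 2-fold and 80% of the 4-fold changes, with 3.2% of its calls false. In petal (23433 genes) it recovered 4% and 66%, and for the interaction (26460 genes) 22% and 70%, both without a false call. Every recovered gene had the right sign. Changes near 2-fold were thus mostly missed in the petal simulation. The changed genes were drawn from the better expressed ones and were far fewer than the genes that passed in the real data (2384 in petal). The adjusted cutoff depends on the share of changed genes, so these percentages are not the power of the real fits.

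Total counts per library are not known, since counts cover called genes alone. Summed over the called genes, counts ran from 1664739 to 3471042 in the corolla libraries and from 811027 to 1710862 in the petal libraries. Counts divided by FPKM give relative depth. Against day 1 repeat 1 of the same tissue, it was 0.829, 0.997 and 0.738 in corolla day 1 repeat 2, day 7 repeat 1 and day 7 repeat 2, from 654 genes. In petal it was 0.812, 0.985 and 0.655 in the same order, from 359 genes. A value of 0 FPKM means only that a gene is listed at 0. Repeats of a group correlated across genes at r = 0.884 to 0.943 on the log2 scale, where genes are not independent, and differed by more than counting noise in 45.0% to 53.8% of the called genes, so no library was taken for a copy of another.

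The labels number the repeats 1 and 2 in each group. Whether a number pairs libraries was checked from the correlation across genes of the repeats' deviations from their group means. Between corolla and petal of the same day the correlation was 0.139 on day 1 and 0.293 on day 7 over 26460 genes. Over 13236 genes with a mean of at least 5 FPKM it was 0.394 and 0.586. The interaction is therefore also given with the repeat number within a day as a block.

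Gene lists, 30 in all, were fixed as text patterns before the data were examined and searched in the descriptions. Descriptions cover only genes the authors called in corolla, petal or both (1929 genes, 468 of them called in both). The lists are thus chosen in part on these samples. A test against all genes would be circular, and each list's split of risers and fallers was compared with that of the other described genes past the threshold by Fisher's exact test, two-sided. Lists with at least 5 members past the threshold were tested, 20 in corolla and 18 in petal, with Benjamini-Hochberg adjustment within a tissue. Lists for mevalonate synthesis, prenyl diphosphate synthases, Amaryllidaceae alkaloids, plant viruses, and fungi and insects had 0 members among the described genes. The pattern for fungi and insects held a few genus names only. Some described genes had best hits in other fungi, such as Rhizopus and Mucor. Text patterns also caught genes of other functions. Such members were marked in 8 lists, among them an acyl-CoA oxidase in the abscisic acid and gibberellin list and a codeine O-demethylase in the flavonoid list. In the heat shock list they were a 26S protease subunit and a cell division control protein 48. The marking was not complete. An isochorismate synthase (c106956.graph_c2) in the shikimate list and a tetraketide alpha-pyrone reductase (c98606.graph_c1) in the lignin list were not marked. The lists were kept as fixed.

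Genes named were fixed by rule before the data were examined. In each tissue the rule took the 6 largest rises and 6 largest falls past the threshold that had a described protein, no overlap between days and a mean of at least 10 FPKM (set for CPM, applied to FPKM). It added up to 2 rising and 2 falling members with the smallest p of each list with 3 or more members past the threshold and of each scent list, and the 5 genes with the smallest p on each side of the interaction. This gave 99 genes in corolla and 92 in petal, of which the text names a part. Values in the other tissue, the Gene Ontology examples and 5 further tissue differences were chosen after their values were seen. Assembled genes with the same description may share reads, which the authors' tables do not resolve.

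Alternatives were median-of-ratios and TMM scaling, other filters or none, a pseudocount of 0.1, the repeat number as a block, a 2-fold minimum, all 8 libraries in 1 fit, the authors' calls, leaving out each library in turn, and leaving out genes listed at 0 in both day 1 and above 0 in both day 7 libraries of the tissue, and leaving out list members whose description does not name the function of the list.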

Results

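Transcript levels were measured in corolla and petal of the scented narcissus cultivar Jinzhanyintai on day 1, at early flowering, and on day 7, at full bloom. The 4 groups held 2 libraries each. Levels are FPKM, given as mean ± SD of 2 libraries, and changes are day 7 against day 1 on the log2(FPKM + 1) scale. At 1 FPKM or more, 23336 to 26172 genes were detected per corolla library and 23508 to 29601 per petal library. The most abundant assembled gene, c73852.graph_c0, held 4.61% to 9.53% of all FPKM in the 8 libraries. Depth differed between libraries, and the shallowest in each tissue was day 7 repeat 2.

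The study addresses floral scent, and the corolla comparison asks which transcripts differ between early flowering and full bloom in that tissue. Enzymes that supply scent precursors rose and fell side by side. Arogenate/prephenate dehydratase 1 (c106196.graph_c0), an enzyme of phenylalanine synthesis, rose from 49.9 ± 3.32 to 351 ± 9.64 FPKM (SD, n = 2; log2 fold change 2.79 ± 0.08 SE, limma adjusted p = 0.00121). DAHP synthase 2 (c99662.graph_c0), at the entry of the shikimate pathway, rose from 1130 ± 323 to 4910 ± 661 FPKM (2.14 ± 0.23, limma adjusted p = 0.00592). Phenylalanine ammonia-lyase 1 (c103612.graph_c0), which turns phenylalanine into cinnamate, fell from 154 ± 12.2 to 12.6 ± 0.0849 FPKM (-3.50 ± 0.10, limma adjusted p = 0.00121). A pair of 1-deoxy-D-xylulose-5-phosphate synthase genes, which feed plastid terpenoid synthesis, moved in opposite directions.

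Of the 4 members of the methylerythritol phosphate pathway list, 2 rose and 2 fell in corolla. The synthase 2 genes c106934.graph_c1 (196 ± 21.6 to 764 ± 72.5 FPKM) and c54414.graph_c0 (7.12 ± 0.672 to 25.9 ± 6.40 FPKM) rose. The synthase 1 gene c107914.graph_c0 (171 ± 13.0 to 42.0 ± 1.94 FPKM) and the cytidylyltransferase of the same pathway (c91750.graph_c0, 18.7 ± 0.113 to 6.33 ± 0.0566 FPKM) fell. The terpene synthase list had 1 member, terpene synthase 4 (c101367.graph_c0), which rose from 1.38 ± 0.368 to 3.76 ± 0.495 FPKM (limma adjusted p = 0.048). Its call ended, among other settings, with a pseudocount of 0.1 (adjusted p = 0.0552) and with no filter on low FPKM (0.15). In the shikimate and phenylalanine list 4 of 8 members rose and 4 fell. In the list of phenylpropanoid entry and benzenoid scent enzymes 5 of 10 rose and 4 fell. Its risers included 4-coumarate-CoA ligase-like 6 (c106335.graph_c1, 45.8 ± 7.12 to 262 ± 35.1 FPKM) and benzyl alcohol O-benzoyltransferase (c95879.graph_c2, 59.4 ± 3.37 to 173 ± 14.3 FPKM), which makes benzyl benzoate. A further phenylalanine ammonia-lyase gene (c78531.graph_c0) was among its fallers, from 40.1 ± 3.87 to 14.0 ± 0.891 FPKM. Adjusted over the list alone these counts were the same. Descriptions exist only for genes the authors had called, so the counts are not independent evidence of direction.

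In the photosynthesis list 39 of 40 members fell in corolla and 0 rose (Fisher's exact test of the split, adjusted p = 2.21e-05), with the same counts adjusted over the list alone. Chlorophyll a-b binding protein 4 (c107054.graph_c2) fell from 94.4 ± 12.7 to 3.33 ± 0.113 FPKM (-4.46 ± 0.14), and photosystem I subunit II (c99335.graph_c0) from 85.1 ± 0.00707 to 5.58 ± 0.00707 FPKM. All 8 members of the chlorophyll synthesis and breakdown list fell, among them protochlorophyllide reductase (c91455.graph_c0, 257 ± 2.64 to 46.2 ± 6.29 FPKM), although the split of the list did not pass (adjusted p = 0.445). In the carotenoid list 10 of 14 fell and 3 rose (adjusted p = 0.902). Phytoene synthase (c101402.graph_c0), the entry enzyme, fell from 342 ± 16.6 to 131 ± 7.33 FPKM, and lycopene epsilon cyclase (c109754.graph_c4) from 117 ± 5.87 to 21.4 ± 0.0990 FPKM. Zeaxanthin epoxidase (c104304.graph_c0, 8.74 ± 2.38 to 74.5 ± 0.276 FPKM) and carotenoid cleavage dioxygenase 4 (c104683.graph_c0, 15.1 ± 6.08 to 61.6 ± 5.03 FPKM) rose. The lignin branch gave 1 riser and 9 fallers of 12 (adjusted p = 0.487; 2 and 9 adjusted over the list alone), with cinnamyl alcohol dehydrogenase (c103687.graph_c0) down from 272 ± 28.8 to 42.4 ± 1.88 FPKM. The flavonoid and anthocyanin list gave 4 and 7 of 12 (adjusted p = 0.902), and chalcone-flavonone isomerase 3 (c94522.graph_c0) fell from 419 ± 17.6 to 75.0 ± 1.80 FPKM. Counts for the chlorophyll, carotenoid and flavonoid lists were the same adjusted over the list alone. These lists, too, hold only genes the authors had called in a tissue.

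Among hormone and regulator genes in corolla, those of the abscisic acid and gibberellin list mostly rose. In that list 15 of 17 tested members rose and 2 fell (Fisher's exact test, adjusted p = 1.26e-05), the same adjusted over the list alone. The 5 members described only through petal calls all rose. Snakin-2 (c96515.graph_c0), of the gibberellin-regulated peptide family, rose from 4.92 ± 3.57 to 327 ± 6.72 FPKM (5.94 ± 0.43), and an ABSCISIC ACID-INSENSITIVE 5-like factor (c105269.graph_c1) from 4.98 ± 1.20 to 43.4 ± 6.90 FPKM. Abscisic acid 8'-hydroxylase 1 (c98134.graph_c0), which breaks the hormone down, fell from 12.2 ± 3.49 to 1.42 ± 0.679 FPKM. All 5 NAC transcription factors rose (adjusted p = 0.0142), and all 5 adjusted over the list alone, 2 of them described only through petal calls. Fewer than 5 NAC genes passed, too few for a test of the split, with no filter on low FPKM (4), with DESeq2 on the called genes (3), without corolla day 7 repeat 1 (4) and without either day 1 library (0). NAC100 (c104534.graph_c0) went from 2.24 ± 0.976 to 36.8 ± 18.7 FPKM. The MYB list had 0 risers and 6 fallers of 8 (adjusted p = 0.445; 2 and 6 adjusted over the list alone), led by Myb305 (c105121.graph_c1), which fell from 410 ± 45.3 to 30.9 ± 13.9 FPKM. MADS-box genes gave 2 risers and 2 fallers of 4, WRKY genes 2 and 1 of 5, and auxin genes 3 and 3 of 8 (adjusted p = 0.524), all unchanged in number adjusted over the list alone. The auxin-conjugating enzyme GH3.1 (c105405.graph_c0) rose from 12.2 ± 1.20 to 113 ± 26.4 FPKM. The jasmonate list had 0 risers and 7 fallers of 9 (adjusted p = 0.445; 0 and 8 adjusted over the list alone), including a 13S-lipoxygenase (c109126.graph_c0, 89.1 ± 11.0 to 17.3 ± 5.83 FPKM). The ethylene list gave 3 and 7 of 13 (adjusted p = 1.00; 5 and 8 adjusted over the list alone). Of its fallers 4 are not ethylene genes by description but were matched by the word alone: methylenetetrahydrofolate reductases of folate metabolism, such as the leading faller c95205.graph_c0, and a sterol methyltransferase. The other 9 members gave 3 and 3.

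The largest falls in corolla were those of the sugar transporter SWEET4 (c54457.graph_c0, 95.8 ± 53.7 to 0.585 ± 0.516 FPKM), a pEARLI1-like lipid transfer protein (c105508.graph_c1, 956 ± 8.65 to 22.0 ± 20.9 FPKM) and a palmitoyl-acyl carrier protein thioesterase (c103026.graph_c0, 74.0 ± 11.4 to 0.770 ± 0.226 FPKM). Trans-resveratrol di-O-methyltransferase (c48302.graph_c0, 3.00 ± 2.22 to 129 ± 15.0 FPKM) and a xyloglucan endotransglucosylase (c98673.graph_c0, 0.795 ± 0.0919 to 89.4 ± 70.1 FPKM) were among the largest rises. The cell wall list had 13 risers and 31 fallers of 51 (adjusted p = 1.00; 14 and 32 adjusted over the list alone). Expansin-A1 (c93401.graph_c0) fell from 19.9 ± 1.70 to 0.185 ± 0.0354 FPKM, while the leading risers were polygalacturonase inhibitors such as c94845.graph_c0 (22.6 ± 4.04 to 145 ± 21.2 FPKM), proteins that block a wall-degrading enzyme. Nutrient and sugar transport genes gave 6 and 10 of 19 (adjusted p = 0.774; 7 and 10 adjusted over the list alone). Senescence genes gave 8 and 11 of 23 (adjusted p = 0.445; 9 and 11 adjusted over the list alone), with autophagy-related protein 8C (c103020.graph_c0) among the risers (log2 fold change 1.21 ± 0.13 SE, limma adjusted p = 0.00629).

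Ribosomal protein genes in corolla counted 13 risers and 46 fallers of 59 (Fisher's exact test, adjusted p = 0.445), the same adjusted over the list alone. The fallers were led by plastid proteins such as 50S L15 (c84916.graph_c0, 152 ± 0.431 to 23.7 ± 2.02 FPKM). Of the 13 risers, 8 were listed at 0 in all day 1 libraries of both tissues and above 0 in all day 7 libraries, and 5 had their best database hit outside land plants. The split passed Fisher's exact test with no filter on low FPKM (0 and 43, adjusted p = 8.17e-05) and with at least 5 FPKM in 2 libraries (0 and 46, 5.55e-06). It also passed without genes listed at 0 on day 1 and above 0 in both day 7 libraries (1 and 46, 2.48e-05). Such genes can only be risers, so leaving them out moves the split towards fallers by construction. The 5 FPKM filter left out the 8 risers listed at 0 on day 1 too, so neither pass is separate support. Heat shock proteins and chaperones gave 2 and 15 of 25 (adjusted p = 0.445; 9 and 16 adjusted over the list alone), and heat shock protein 81-2 (c100056.graph_c0) fell from 386 ± 20.6 to 97.2 ± 14.8 FPKM. Small heat shock genes differed between the day 1 repeats, being higher in repeat 2 for 6 of 7 genes in both tissues, by a median log2 of 1.73 in corolla and 1.45 in petal. In corolla all of these 7 genes but c96897.graph_c0, which fell, were higher in both day 7 libraries than in both day 1 libraries. Gene c100136.graph_c0 stood at 46.8 and 157.4 FPKM on day 1 and at 345.14 and 297.19 FPKM on day 7. Only 2 members of the whole list rose past the threshold. Glutathione S-transferases and peroxidases gave 5 and 6 of 12 (adjusted p = 0.487; 6 and 6 adjusted over the list alone). The cell cycle list, which holds kinesins (motor proteins with roles beyond division as well), histones and an RNA-directed DNA polymerase homolog, gave 1 and 4 of 7 (adjusted p = 1.00; 1 and 6 adjusted over the list alone), and pollen and anther markers 0 and 4 of 7, the same adjusted over the list alone.

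Of 22407 genes tested in corolla, 4820 passed limma's FDR of 0.05, with 1462 rising and 3358 falling. TMM scaling moved the split to 2004 rising and 2838 falling, and with no filter on low FPKM 2452 genes passed. The authors' deposited table called 1707 genes in corolla, of which 1658 were tested here, and 1587 of these (95.7%) passed with the same sign. The count rests on each library: it was 0 without day 1 repeat 1 or without day 1 repeat 2 (5139 and 5551 genes at an unadjusted limma p under 0.05), 2434 without day 7 repeat 1 and 2932 without day 7 repeat 2.

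**Figure D1:**
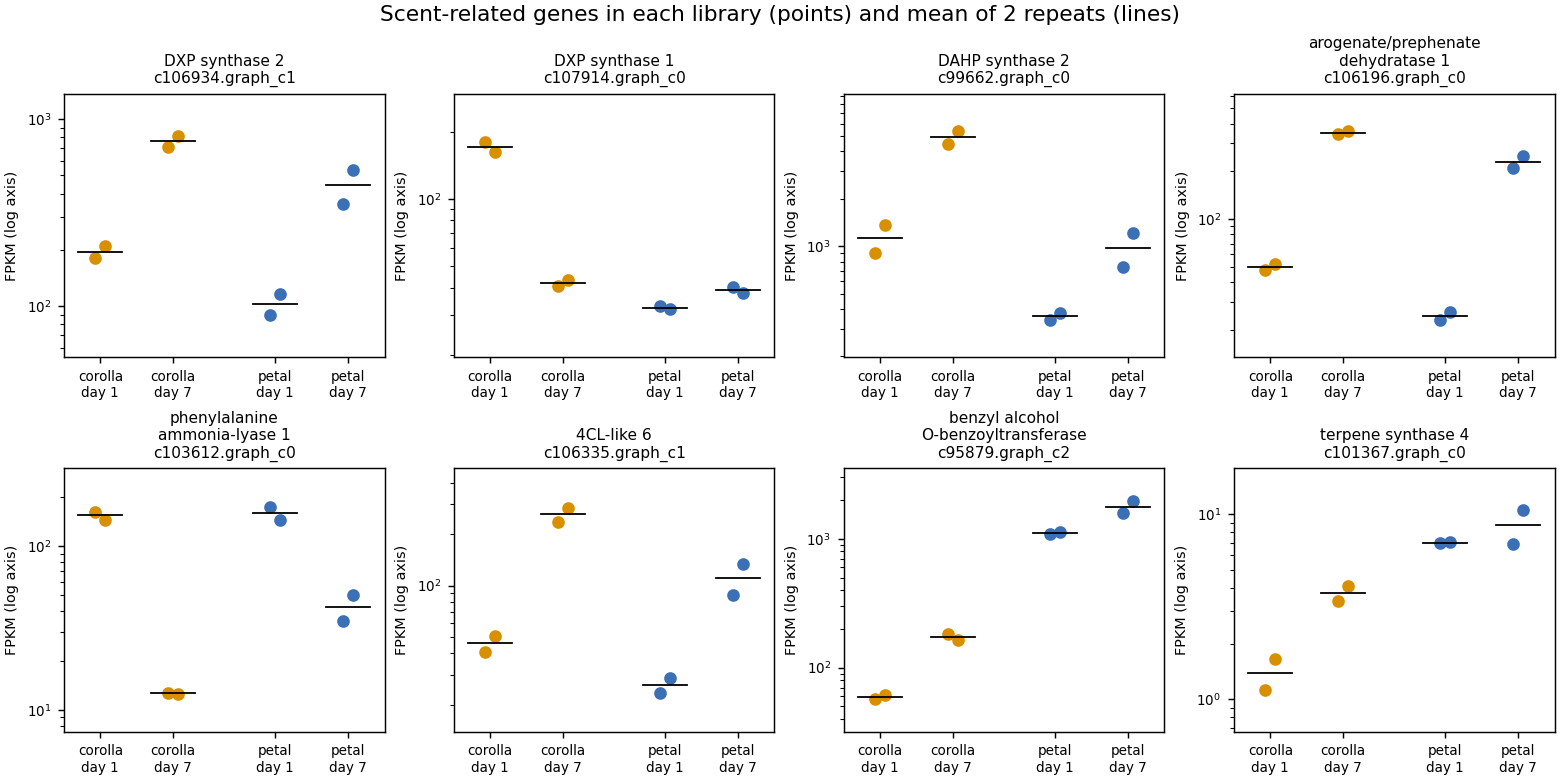
FPKM on a log axis of 8 scent-related genes in the 8 libraries; points are libraries and lines are the mean of 2 repeats of a group. Arogenate/prephenate dehydratase 1 stood at 351 FPKM in corolla on day 7 against 49.9 on day 1 and at 230 against 24.6 in petal. Phenylalanine ammonia-lyase 1 fell in both tissues. Benzyl alcohol O-benzoyltransferase, terpene synthase 4 and 1-deoxy-D-xylulose-5-phosphate synthase 1 did not pass the test in petal. The benzoyltransferase passed there under median-of-ratios and TMM scaling and with all 8 libraries in 1 fit.

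The petal comparison asks the same question of the other tissue. Arogenate/prephenate dehydratase 1 (c106196.graph_c0) rose in petal from 24.6 ± 2.02 to 230 ± 29.2 FPKM (SD, n = 2; log2 fold change 3.16 ± 0.15 SE, limma adjusted p = 0.00447). The 1-deoxy-D-xylulose-5-phosphate synthase 2 gene c106934.graph_c1 rose from 103 ± 19.3 to 444 ± 128 FPKM (2.08 ± 0.25, limma adjusted p = 0.0145), and DAHP synthase 2 (c99662.graph_c0) from 358 ± 25.0 to 978 ± 344 FPKM (1.40 ± 0.28, limma adjusted p = 0.0415). Phenylalanine ammonia-lyase 1 (c103612.graph_c0) fell from 159 ± 20.9 to 42.6 ± 11.0 FPKM (-1.89 ± 0.22, limma adjusted p = 0.0123), and a further phenylalanine ammonia-lyase (c93919.graph_c0) from 20.0 ± 5.66 to 1.85 ± 0.417 FPKM.

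Benzyl alcohol O-benzoyltransferase (c95879.graph_c2) was abundant in petal on both days, at 1100 ± 27.6 and 1780 ± 256 FPKM, and did not pass (limma adjusted p = 0.134), although it rose under median-of-ratios scaling (0.0466), TMM scaling (0.0386) and with all 8 libraries in 1 fit (0.0154). Terpene synthase 4 (c101367.graph_c0) stood at 7.01 ± 0.0424 and 8.69 ± 2.58 FPKM (limma adjusted p = 0.569), so the terpene synthase list had 0 risers and 0 fallers, also adjusted over the list alone. In the methylerythritol phosphate pathway list 1 of 4 rose and 0 fell (2 and 1 adjusted over the list alone). Shikimate and phenylalanine synthesis gave 2 risers and 1 faller of 8 (4 and 2 adjusted over the list alone). Phenylpropanoid entry and benzenoid scent enzymes gave 4 and 4 of 9 (Fisher's exact test, adjusted p = 0.628; 5 and 4 adjusted over the list alone), with 4-coumarate-CoA ligase-like 6 (c106335.graph_c1) up from 26.0 ± 3.52 to 111 ± 32.0 FPKM. The lignin branch gave 3 and 6 of 12 (adjusted p = 1.00; 3 and 8 adjusted over the list alone), and the flavonoid and anthocyanin list 1 and 6 of 12 (adjusted p = 0.628; 4 and 8 adjusted over the list alone). Carotenoid genes gave 1 and 4 of 13 (adjusted p = 0.815; 1 and 5 adjusted over the list alone). Zeaxanthin epoxidase (c104304.graph_c0) rose from 28.5 ± 5.01 to 119 ± 28.3 FPKM, whereas carotenoid cleavage dioxygenase 4 (c104683.graph_c0), at 464 ± 49.1 and 284 ± 53.5 FPKM, did not pass (limma adjusted p = 0.0799), although it fell under median-of-ratios scaling (0.0392), TMM scaling (0.0418) and with at least 5 FPKM in 2 libraries (0.0449). As in corolla, only genes called by the authors carry descriptions, which leaves these counts without independent weight on direction.

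In petal 14 of 19 members of the abscisic acid and gibberellin list rose and 1 fell (Fisher's exact test, adjusted p = 3.91e-05; 16 and 1 adjusted over the list alone). Of its 5 members described only through corolla calls, 1 rose and 0 fell in petal. Gibberellin 2-beta-dioxygenase (c101837.graph_c0), which inactivates gibberellins, rose from 1.44 ± 0.651 to 57.9 ± 20.7 FPKM (4.57 ± 0.32), and snakin-2 (c96515.graph_c0) from 4.38 ± 1.18 to 71.2 ± 8.63 FPKM. All 5 NAC genes rose (adjusted p = 0.0193; all 5 adjusted over the list alone), 3 of them described only through corolla calls, and NAC48 gene c97748.graph_c0 went from 3.76 ± 1.63 to 68.8 ± 9.39 FPKM. The NAC split could not be tested with no filter on low FPKM (3 genes passed), with DESeq2 on the called genes (2), without petal day 7 repeat 2 (3) or without any of the other petal libraries (0). Ribosomal protein genes had 0 risers and 26 fallers of 47 (adjusted p = 0.000232; 1 and 40 adjusted over the list alone). Members listed at 0 in all day 1 libraries and above 0 in all day 7 libraries gave 8 of the 13 corolla risers. In petal day 7 repeat 1 such members stood at 0.14 to 0.86 FPKM, so the filter kept them out of the petal test. The petal pass beside the failed corolla split is thus no evidence of a tissue difference. The list holds many plastid ribosomal proteins, so it may not be independent of the photosynthesis list. Photosynthesis genes had 0 and 17 of 33 (adjusted p = 0.00728; 0 and 28 adjusted over the list alone), with the small chain of ribulose bisphosphate carboxylase (c89121.graph_c0) down from 134 ± 5.58 to 28.5 ± 5.49 FPKM. Heat shock proteins and chaperones had 0 and 13 of 24 (adjusted p = 0.0227; 1 and 15 adjusted over the list alone), led by heat shock protein 81-3 (c94919.graph_c1, 263 ± 13.8 to 34.1 ± 0.354 FPKM). The heat shock call ended under median-of-ratios scaling (adjusted p = 0.0629) and TMM scaling (0.0979), with at least 5 FPKM in 2 libraries (0.108), with no filter on low FPKM (0.201), with DESeq2 on the called genes (0.061) and without petal day 7 repeat 2 (0.10). The photosynthesis call ended with no filter (adjusted p = 0.201), with DESeq2 on the called genes (0.0505) and without petal day 7 repeat 2 (0.10), and the ribosomal protein call with DESeq2 on the called genes (0.0771). With no filter 4 ribosomal protein genes passed, too few for a test. Since the authors' calls decided which genes are described, these splits are not independent evidence either.

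The largest falls in petal were those of a putative cell wall protein (c101821.graph_c0, 878 ± 328 to 6.20 ± 0.163 FPKM), endoglucanase 19 (c105014.graph_c0, 284 ± 43.4 to 6.62 ± 1.07 FPKM) and a GDSL esterase/lipase (c99501.graph_c0, 2390 ± 505 to 74.3 ± 4.36 FPKM). The largest rises included amino acid permease 1 (c103185.graph_c1, 5.37 ± 2.55 to 208 ± 72.0 FPKM), which imports amino acids, trans-resveratrol di-O-methyltransferase (c48302.graph_c0, 7.22 ± 4.09 to 205 ± 11.6 FPKM) and a mitochondrial ADP,ATP carrier (c104460.graph_c1, 6.73 ± 0.0495 to 172 ± 46.7 FPKM). Myb305 (c105121.graph_c1) fell from 458 ± 24.4 to 25.2 ± 4.24 FPKM. The MYB list gave 3 and 2 of 9 (Fisher's exact test, adjusted p = 0.628; 3 and 4 adjusted over the list alone). The cell wall list gave 10 and 28 of 51 (adjusted p = 0.628; 13 and 33 adjusted over the list alone), and xyloglucan endotransglucosylase c98673.graph_c0 rose from 34.0 ± 3.66 to 564 ± 176 FPKM. The jasmonate list gave 1 and 8 of 9 (adjusted p = 0.628; 1 and 8 adjusted over the list alone), its riser being 9S-lipoxygenase 5 (c107209.graph_c2, 51.7 ± 31.0 to 241 ± 36.6 FPKM). Senescence genes gave 6 and 12 of 22 (adjusted p = 1.00; 9 and 12 adjusted over the list alone). Cysteine proteinase inhibitor 1 (c111264.graph_c0), which blocks such proteases, was the list's largest faller, from 432 ± 63.1 to 18.6 ± 17.2 FPKM.

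Nutrient and sugar transport gave 6 risers and 5 fallers of 18 in petal (Fisher's exact test, adjusted p = 0.508; 8 and 8 adjusted over the list alone), the ethylene list 2 and 6 of 13 (adjusted p = 0.815; 5 and 8 adjusted over the list alone), or 2 and 4 of 9 without the folate and sterol enzymes it caught, and auxin genes 4 and 4 of 10 (adjusted p = 0.628; the same adjusted over the list alone). Glutathione S-transferases and peroxidases gave 5 and 4 of 12 (adjusted p = 0.508; the same adjusted over the list alone). Pollen and anther markers gave 3 and 4 of 7 (adjusted p = 0.815; the same adjusted over the list alone), with a pollen-specific protein (c97442.graph_c0) down from 53.0 ± 18.3 to 1.28 ± 0.905 FPKM. MADS-box genes gave 1 and 2 of 4 (2 and 2 adjusted over the list alone), WRKY genes 2 and 1 of 5 (2 and 3), the list of kinesins, histones and an RNA-directed DNA polymerase homolog 1 and 2 of 7 (2 and 4) and chlorophyll genes 0 and 2 of 7 (0 and 5).

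Of 23433 genes tested in petal, 2384 passed limma's FDR of 0.05, with 966 rising and 1418 falling. The authors' deposited table called 1053 genes in petal, of which 1035 were tested here, and 938 of these (90.6%) passed with the same sign. With no filter on low FPKM the count was 452, and 25 of the 92 petal genes taken by the rule lost their call, among them DAHP synthase 2 (adjusted p = 0.144; 0.0521 with a pseudocount of 0.1), synthase 2 gene c106934.graph_c1 (0.0518), ECERIFERUM 1 (0.0524), S-norcoclaurine synthase (0.0872), 9S-lipoxygenase 5 (0.113) and cysteine proteinase inhibitor 1 (0.0625). With all 8 libraries in 1 fit 3921 genes passed. The count was 0 without day 1 repeat 1, day 1 repeat 2 or day 7 repeat 1 (3186, 3594 and 6603 genes at an unadjusted limma p under 0.05) and 2164 without day 7 repeat 2.

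**Figure D2:**
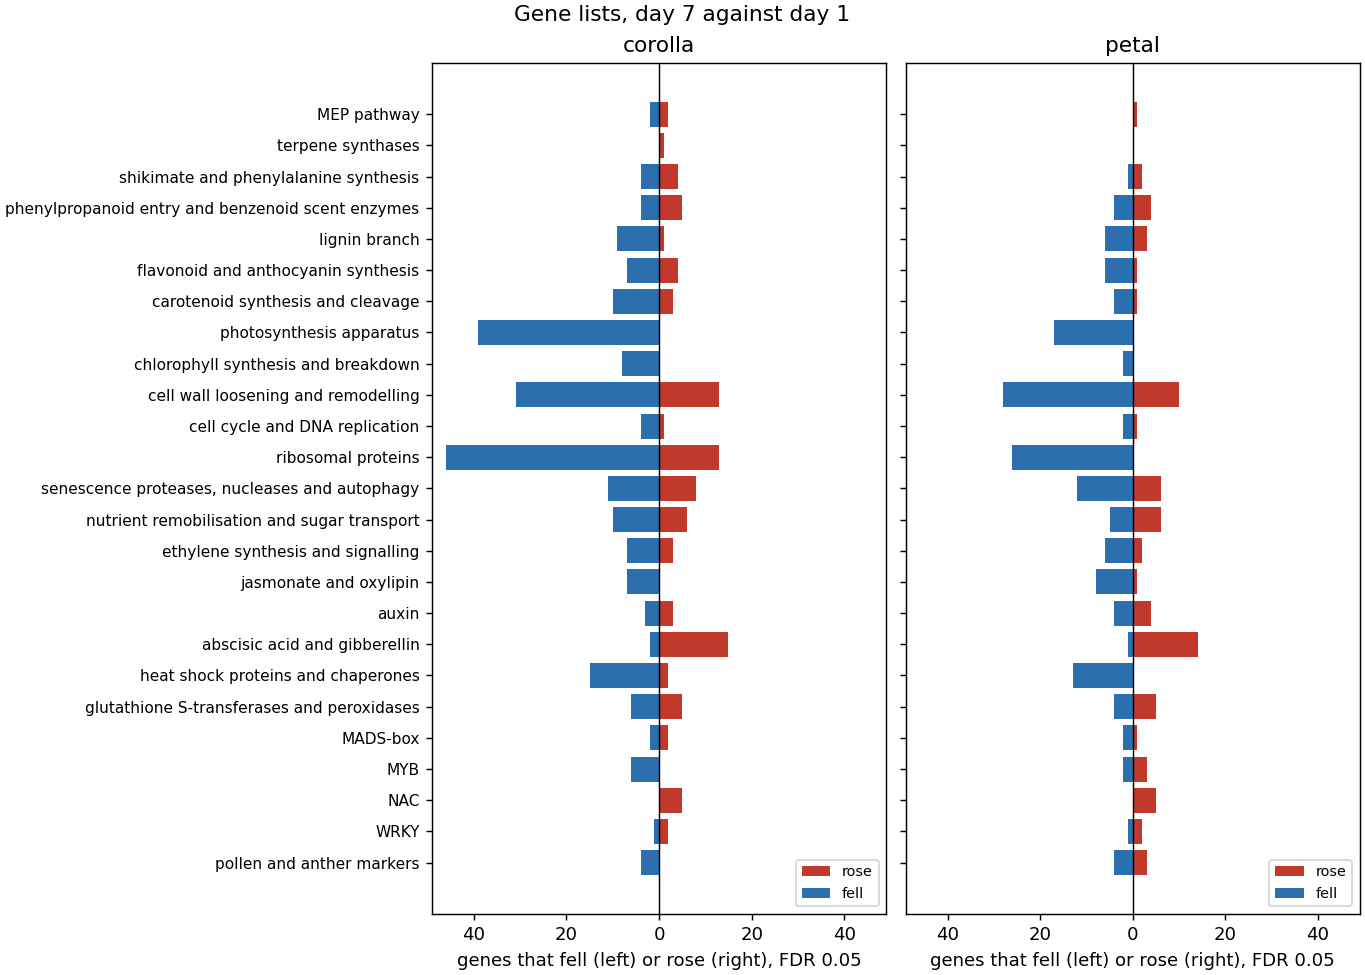
Number of members of each gene list with described genes that rose (right) or fell (left) at an FDR of 0.05, in corolla and petal. Photosynthesis genes counted 39 fallers in corolla and 17 in petal, and genes of the abscisic acid and gibberellin list 15 and 14 risers.

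Among 20355 genes tested in both, 407 rose in both against 52.5 for independent lists, and 992 fell in both against 205.9, while 14 passed in opposite directions. Repeats of the same number deviated together in corolla and petal of a day (correlations across genes of 0.139 and 0.293), which can raise such an overlap. How far it did so was not tested, so the size of the excess is not a measure of shared day effects. Whether a day effect differed between tissues was tested by the interaction. The 1-deoxy-D-xylulose-5-phosphate synthase 1 gene c107914.graph_c0 fell in corolla and stood at 32.4 ± 0.714 and 39.0 ± 1.82 FPKM in petal (SD, n = 2; difference of log2 fold changes -2.26 ± 0.16 SE, limma adjusted p = 0.0023). ECERIFERUM 1 (c103187.graph_c0), an enzyme of wax synthesis, fell in corolla from 15.4 ± 0.276 to 2.78 ± 0.0283 FPKM and rose in petal from 62.1 ± 5.60 to 133 ± 3.25 FPKM (-3.20 ± 0.17, limma adjusted p = 0.000727). S-norcoclaurine synthase (c106745.graph_c0) fell in both, from 1440 ± 126 to 162 ± 4.62 FPKM in corolla and from 98.9 ± 9.02 to 55.2 ± 0.389 FPKM in petal (-2.32 ± 0.17, limma adjusted p = 0.00243).

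On the other side, a trypsin inhibitor (c96639.graph_c0) stood at 82.5 ± 7.26 and 96.1 ± 24.3 FPKM in corolla and fell in petal from 338 ± 53.4 to 28.3 ± 0.00 FPKM (difference 3.72 ± 0.26, limma adjusted p = 0.0023). Lysine histidine transporter 1 (c106200.graph_c0), an amino acid importer, rose in corolla from 1.33 ± 0.0849 to 20.0 ± 2.62 FPKM and stood at 11.3 ± 1.80 and 13.7 ± 3.13 FPKM in petal (2.92 ± 0.29, limma adjusted p = 0.00828; 0.0623 without corolla day 1 repeat 1). Carotenoid cleavage dioxygenase 4 (c104683.graph_c0) differed by 2.73 ± 0.35 (limma adjusted p = 0.020), phytoene synthase (c101402.graph_c0) by -1.75 ± 0.28 (limma adjusted p = 0.0407) and phenylalanine ammonia-lyase 1 (c103612.graph_c0) by -1.61 ± 0.26 (limma adjusted p = 0.0403). With no filter on low FPKM the differences of phytoene synthase (adjusted p = 0.0663) and phenylalanine ammonia-lyase 1 (0.0655) no longer passed, and that of phytoene synthase also failed under median-of-ratios scaling (0.0556) and with a pseudocount of 0.1 (0.0835). The phytoene synthase call ended without any 1 library other than petal day 7 repeat 2, and the ammonia-lyase call without any 1 library other than the petal day 7 repeats. That of the dioxygenase ended without corolla day 1 repeat 1, corolla day 7 repeat 2, either petal day 1 repeat or petal day 7 repeat 1 (adjusted p = 0.0585 to 0.114). Chlorophyll synthesis genes fell further in corolla, 5 of 8 past the threshold on that side and 0 on the other. Of 39 photosynthesis genes 4 passed on that side and 0 on the other, and 35 had a difference below 0, with a median of -1.42 against -0.01 over all genes tested. Both lists were described mainly through corolla calls, so these counts are not independent of the authors' choice. Among the scent lists, arogenate/prephenate dehydratase 1 and DAHP synthase 2 did not pass the test of the difference (-0.37 and 0.74, limma adjusted p = 0.509 and 0.554).

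In all, 173 of 26460 genes passed limma's FDR of 0.05 for the interaction, 69 with a higher and 104 with a lower day effect in corolla. Under median-of-ratios scaling 270 passed (117 higher, 153 lower), and with no filter on low FPKM 99 passed (45 and 54). The lean towards lower effects turned without corolla day 7 repeat 2 (56 higher, 39 lower), petal day 7 repeat 2 (115 and 101) or corolla day 1 repeat 2 (26 and 20). With the repeat number within a day as a block, a fit chosen after the data were seen, 335 genes passed, 162 higher and 173 lower. The count ran from 14 without corolla day 1 repeat 1 to 216 without petal day 7 repeat 2, and the other libraries that moved it by over 1.5 times were corolla day 1 repeat 2 (46), corolla day 7 repeat 2 (95), petal day 1 repeat 1 (20), petal day 1 repeat 2 (42) and petal day 7 repeat 1 (84).

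**Figure D3:**
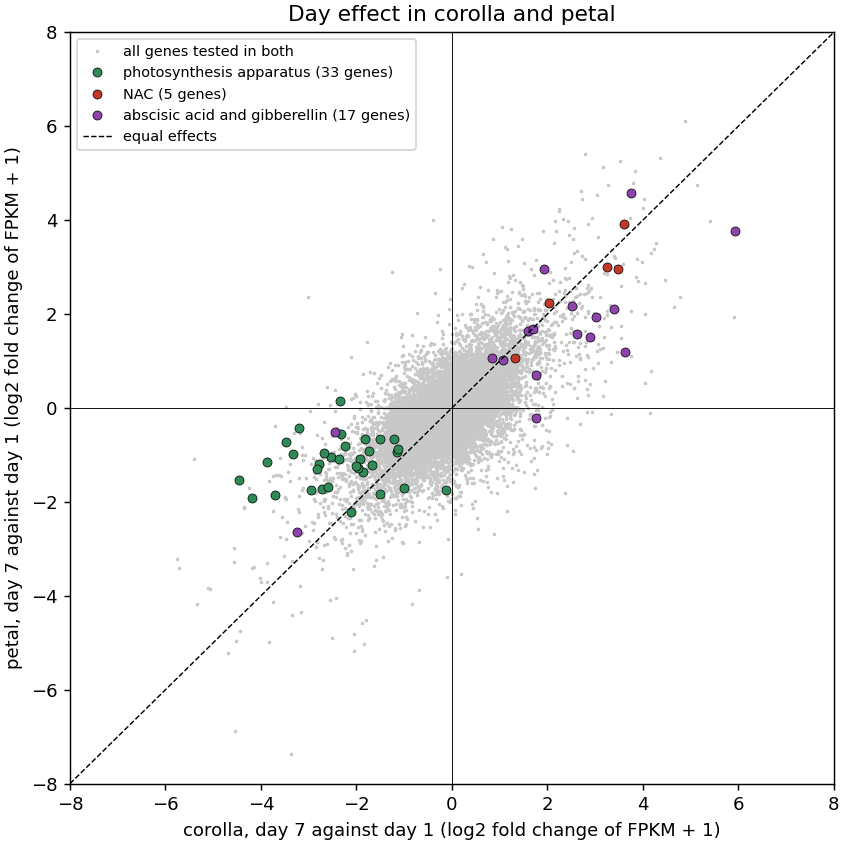
Log2 fold change of FPKM + 1, day 7 against day 1, in corolla (horizontal axis) and petal (vertical axis) for 20355 genes tested in both tissues (grey points); coloured points are members of 3 lists and the dashed line marks equal effects. Of the 33 photosynthesis genes shown, 29 lie above the line, while the 5 NAC genes lie at the upper right.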

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

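The tests of explanations in this part were chosen after the results had been seen, and the move of the interaction to limma was made once the unit of the tables was known. The items given here are differences between corolla and petal in the day effect, each found by the test of the difference itself.

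In all 173 genes differed. Those with a lower day effect in corolla than in petal included ECERIFERUM 1 (c103187.graph_c0, difference of log2 fold changes -3.20), the short-chain dehydrogenase TIC 32 (c90015.graph_c0, -3.05), 1-deoxy-D-xylulose-5-phosphate synthase 1 (c107914.graph_c0, -2.26), S-norcoclaurine synthase (c106745.graph_c0, -2.32) and palmitoyl-acyl carrier protein thioesterase (c103026.graph_c0, -4.31). Palmitoyl thioesterase was already low in petal on day 1, at 1.72 ± 0.0424 FPKM (SD, n = 2), which leaves no room for a fall of the corolla size on the log2(FPKM + 1) scale. Those with a higher day effect in corolla included a trypsin inhibitor (c96639.graph_c0, 3.72), a polygalacturonase (c105277.graph_c0, 2.23), serine carboxypeptidase-like 26 (c110034.graph_c1, 2.08), lysine histidine transporter 1 (c106200.graph_c0, 2.92) and xyloglucan endotransglucosylase 2 (c96460.graph_c3, 3.38). Xyloglucan endotransglucosylase 2 lost its call with a pseudocount of 0.1 (limma adjusted p = 0.0603) and without petal day 1 repeat 1 (0.0655). Serine carboxypeptidase-like 26 lost its call without that library (limma adjusted p = 0.0608) or without corolla day 1 repeat 1 (0.0601), as did the polygalacturonase (0.0601) and lysine histidine transporter 1 (0.0623) without corolla day 1 repeat 1. The polygalacturonase fell in petal from 213 ± 5.95 to 46.9 ± 8.01 FPKM and stood at 31.0 ± 0.870 and 32.6 ± 2.50 FPKM in corolla.

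The pattern weighed here is that of the photosynthesis list, whose median member fell further in corolla (median difference -1.42, 95% bootstrap interval over members -1.72 to -0.84, 35 of 39 below 0). Of these 39 members 4 passed the test of the difference on that side and 0 on the other. The intervals given here resample members measured in the same 8 libraries. They carry no spread between repeats, so they describe these libraries alone. Low petal values compressed by the pseudocount are argued against as the whole cause, since the 22 members with at least 10 FPKM in petal on day 1 kept a median of -1.07 (interval -1.51 to -0.59). Library scaling is argued against as well, with a median of -1.41 (interval -1.71 to -0.84) under median-of-ratios scaling. The choice of members through the authors' corolla calls stays open: the 13 members called in petal had a median of -0.77 with an interval of -1.20 to 0.10, too few to decide. A tissue difference in the loss of photosynthetic transcripts stays open as an untested biological explanation. The median member stood at 85.1 to 85.2 FPKM in the corolla libraries of day 1 and at 12.5 to 17.5 FPKM in those of petal. On day 7 it stood at 9.7 to 11.8 FPKM in corolla and at 7.3 to 9.1 FPKM in petal. Corolla thus started higher and ended near the petal level.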

How the results depend on the processing

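TMM scaling, the pseudocount of 0.1, the filters at a set FPKM, the block within a day, the removal of genes appearing on day 7, the limma test of the interaction and, for the lists, the fits with no filter, with all 8 libraries or without members of other functions were chosen after seeing the data. DESeq2 and a count filter over all genes, the contrasts of corolla with petal within a day, and DESeq2 for the interaction were not run.

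The corolla count (4820) stayed within 1.5 times under both scalings, both FPKM filters, a pseudocount of 0.1, all 8 libraries in 1 fit, and without genes appearing on day 7 (4633). It moved to 2452 with no filter on low FPKM, where 64490 genes were tested, to 2468 with a 2-fold minimum and to 1707 for the authors' calls. The petal count (2384) stayed within 1.5 times under both scalings, both filters, a pseudocount of 0.1, a 2-fold minimum and without genes appearing on day 7 (2649). It moved to 452 with no filter, where 67182 genes were tested, to 3921 with all 8 libraries in 1 fit and to 1053 for the authors' calls. The interaction count (173) moved to 270 under median-of-ratios scaling and to 99 with no filter. The cause of the moves under 8 libraries or scaling was not tested. The 8 list splits that passed, over both tissues, became 4 with no filter and 3 with DESeq2 on the called genes. Fewer genes entered with DESeq2. The 4 with no filter included the corolla ribosomal protein split, which was not among those 8. At both settings NAC, and with no filter petal ribosomal proteins, kept under 5 passing members and had no value. Without the members marked as of other functions, no list call changed (Fisher's exact test, abscisic acid and gibberellin adjusted p = 2.1e-05 in corolla and 0.000111 in petal, petal heat shock 0.0227). That marking was not complete.

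Leaving out 1 library leaves a group with 1 library, which limma then assumes to vary like the others. The counts ranged from 0 to 2932 in corolla (0 without either day 1 library), from 0 to 2164 in petal (0 without either day 1 library or day 7 repeat 1), from 14 to 216 for the interaction and from 3 to 8 for the lists. The list count was 3 without petal day 1 repeat 1, petal day 1 repeat 2 or petal day 7 repeat 1, and 5 without petal day 7 repeat 2 or either corolla day 1 library; NAC had no value without petal day 7 repeat 2 or corolla day 7 repeat 1, and no list of a tissue had one where its gene count was 0. At an unadjusted limma p under 0.05 the counts of 0 were 5139 and 5551 in corolla and 3186, 3594 and 6603 in petal. DESeq2 and edgeR were not run on these subsets. A polygalacturonase (c105277.graph_c0) turned to -0.01 in corolla without corolla day 7 repeat 1 (range -0.01 to 0.14), and a trypsin inhibitor (c96639.graph_c0) to -0.06 without corolla day 7 repeat 2 (range -0.06 to 0.46); neither had passed in corolla. Terpene synthase 4 (c101367.graph_c0), which had not passed in petal, turned to -0.03 there without petal day 7 repeat 2 (range -0.03 to 0.52). The cause of these turns was not tested.

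Repeat numbers do not pair the days within a tissue: deviations correlated at -0.005 in corolla and 0.001 in petal. With the repeat number as a replicate block within a tissue, 3403 genes passed in corolla and 2288 in petal, and the interaction count was 62 (28 higher and 34 lower in corolla). That block ended the call of 3 of the 99 corolla genes, terpene synthase 4 (c101367.graph_c0, adjusted p = 0.0732) among them, of 1 of the 92 petal genes, and of the tissue differences of phytoene synthase (0.137) and phenylalanine ammonia-lyase 1 (0.129); it changed no list call. With the replicate block of repeat within day, which pairs corolla and petal, the interaction count was 335.

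Over all alternatives, the 99 corolla genes kept direction and side of the threshold in 1056 fits and lost the call in 221, and the 92 petal genes kept them in 882, lost the call in 308 and gained it in 2. Total depth is not known, and relative depth fell to 0.738 in corolla and 0.655 in petal day 7 repeat 2, which limits weakly expressed genes most. With the spread of these repeats, limma recovered 4% of the simulated 2-fold changes over 23433 petal genes and 40% over 22407 corolla genes. That simulation changed only 100 genes 2-fold and 100 genes 4-fold, and the adjusted cutoff depends on the share of changed genes. How often the real petal fit missed changes of that size is thus not known. Absence of a call in petal is no evidence of absence of a change.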

Other observations

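The tests of explanations and the choice of Gene Ontology terms and genes in this part were made after the values were seen. Descriptions cover only genes the authors called, so the splits given are not independent evidence of direction. The Gene Ontology splits were not rerun under the alternatives.

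Of the genes with the Gene Ontology term for fatty acid synthesis, 23 fell in corolla and 0 rose (Fisher's exact test of the split, adjusted p = 0.0142 over 125 terms). ECERIFERUM 3 (c109443.graph_c1), an enzyme of cuticular wax synthesis, fell from 723 ± 80.0 to 121 ± 0.346 FPKM (SD, n = 2). The 3-ketoacyl-CoA synthases that elongate very long chain fatty acids fell as well, gene c102727.graph_c0 from 207 ± 24.3 to 20.2 ± 4.49 FPKM, gene c96585.graph_c0 from 127 ± 19.6 to 14.1 ± 1.32 FPKM and gene c99900.graph_c0 from 16.2 ± 0.0707 to 0.480 ± 0.410 FPKM. A plastid acyl carrier protein (c90713.graph_c0) fell from 226 ± 10.7 to 85.1 ± 6.26 FPKM. Chloroplast stroma was the term with the smallest p, at 84 fallers and 0 risers (adjusted p = 6.59e-10). Zinc ion binding leaned the other way with 16 risers and 13 fallers (Fisher's exact test, adjusted p = 0.0113). Its risers included B-box protein 19 (c102677.graph_c0, 8.26 ± 1.14 to 36.9 ± 3.61 FPKM) and a thaumatin-like protein (c109421.graph_c0, 692 ± 51.5 to 3100 ± 185 FPKM). The member with the smallest limma p was a faller, histone deacetylase 15 (c100155.graph_c0, 326 ± 19.8 to 53.4 ± 1.9 FPKM). In petal the fatty acid term also leaned towards falls without passing, at 18 fallers and 2 risers (Fisher's exact test, adjusted p = 0.119 over 81 terms).

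In petal, 15 genes of the protein folding term fell and 0 rose (Fisher's exact test, adjusted p = 0.0358 over 81 terms). Many of them, such as endoplasmin (c99591.graph_c0), are also in the heat shock list, so this split is not separate from that list. The petal call of the heat shock list ended under both scalings, among other settings. The 15 genes included endoplasmic reticulum chaperones. Calreticulin (c102506.graph_c0) fell from 191 ± 9.82 to 72.4 ± 7.43 FPKM (SD, n = 2), calnexin (c86581.graph_c0) from 60.9 ± 3.30 to 17.8 ± 0.580 FPKM and endoplasmin from 110 ± 15.0 to 40.9 ± 8.42 FPKM. The methylation term had 21 fallers and 0 risers (adjusted p = 0.00751). Of these 8 are described as probable methyltransferases of the PMT family, such as PMT21 (c108907.graph_c0, 767 ± 63.2 to 205 ± 24.9 FPKM), and 3 as methionine synthases, such as c109941.graph_c2 (717 ± 88.1 to 231 ± 47.0 FPKM). With no filter on low FPKM the calls of endoplasmin (limma adjusted p = 0.0625) and of this synthase (0.0569) ended. Both terms leaned towards falls in corolla too without passing, with 21 fallers and 1 riser for protein folding and 26 and 3 for methylation. Fisher's exact test gave adjusted p = 0.0964 and 0.153 over the 125 corolla terms.

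A set of 249 genes was listed at 0 in all 4 day 1 libraries and above 0 in all 4 day 7 libraries, against 137 the other way. Of the 25 with a best-hit species, 14 (56.0%) had it outside land plants, against 6 of 1889 (0.318%) of the other described genes (Fisher's exact test, p = 1.73e-24), so reads of another organism in the day 7 samples are a candidate source. Of the other 235 members, 49.8% (95% Wilson interval 43.4% to 56.1%) were lowest in petal day 7 repeat 1, the library in which the median of those 14 was lowest, against 29.6% of 9568 other genes of like level, which is consistent with such reads making up more of the set than the 14. Deeper sequencing on day 7 is argued against, since the shallowest corolla library, at a relative depth of 0.738, and the shallowest petal library, at 0.655, were both day 7 repeat 2. Some of the 14 were lowest elsewhere, such as c36976.graph_c0 at 0.4 FPKM in corolla day 7 repeat 2 and 1.93 in petal day 7 repeat 1. The set is small in amount, at 166.0 to 286.5 FPKM summed per day 7 library. Best hits of the 14 included Rhizopus, Phytophthora and Ectocarpus, so whether such reads came from a single organism stays open. It also stays open whether their source lived on the flowers or entered later, and whether some members are narcissus genes first expressed at full bloom.

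Repeats of the same number deviated together in corolla and petal of the same day. Lower depth of repeat 2, which held in all 4 groups, is argued against as the cause, because the deviations did not correlate between days of a tissue (-0.005 in corolla and 0.001 in petal over all genes tested). A source shared by both tissues of a repeat, such as the flowers, the sampling or a library batch, may be at work: over genes with a mean of at least 5 FPKM, which carry less counting noise, the lower of the correlations was 0.394. Which of these it was cannot be read from the labels and was not tested. On day 1, 6 of 7 small heat shock genes were higher in repeat 2 in both tissues, as with c89093.graph_c0 at 3.25 and 28.48 FPKM in corolla day 1 repeats 1 and 2 and at 1.09 and 21.15 FPKM in petal.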
